A study of Zea mays with 6 samples.

How the data were processed

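Transcripts were measured by RNA sequencing in 6 libraries of young maize ears: 2 each of wild type, the RHW1 knockout and 1 RHW1 overexpression line. Total RNA was extracted with a plant kit and treated with DNase, and libraries were made with the NEBNext Ultra II kit, per the labels' protocols; how messenger RNA was selected and whether strand was kept are not given in the sources used here. The deposited table holds raw read counts per gene for each library, not normalized, as its whole numbers with unequal totals show. The submitters' processing notes name Trimmomatic 0.35, HISAT2 2.1.0, HTSeq, edgeR 3.32.1 and StringTie, without roles or order. The genome build, the annotation and the counting options are not given in the sources used here. Without a stated use of strand, reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies have uncertain counts. One such pair is zma-MIR528a and zma-MIR528b, which give the same mature microRNA, and zma-MIR408b overlaps 1 long non-coding RNA gene in the reference table.

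The table has 45578 genes: 43789 with Zm00001d identifiers, 1635 with ENSRNA identifiers and 154 microRNA genes. The reference table of RefSeq genes (assembly Zm-B73-REFERENCE-NAM-5.0) matched 153 of the microRNA names and 0 of the other identifiers. Hence genes other than microRNA genes appear by identifier, without coordinates or functions, and the prefix that the table puts before each identifier was dropped. Before the data were examined, 29 gene lists (developmental regulators, cell division, hormones, photosynthesis, stress and markers of other tissues) had been fixed by gene name; 0 of them could be tested, because no listed name matched an identifier. The tests of RHW1, ZCN4 and the lists were therefore not made. The number of columns left unused was 0.

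Genes were kept with edgeR's filterByExpr (minimum count 10), which left 22947 genes holding 99.9% of the reads in every library. Of these, 22824 had Zm00001d identifiers, 113 ENSRNA identifiers and 10 were microRNA genes. Counts were scaled by TMM factors of 0.991 to 1.01 and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F-test in 1 fit of all 6 libraries with 3 group means, which has 3 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison and called below 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The biological coefficient of variation was 3.82%. The prior that edgeR drew from all genes had 33.2 degrees of freedom. The spread used for a gene thus rested mostly on that of all genes. The median log2 fold change of all genes lay between -0.005 and 0.001 in the 3 comparisons. CPM values are counts scaled to library size and TMM factor, with no pseudocount; log2 CPM for the principal components, correlations and covariances used a prior count of 2.

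The test was checked on simulated counts with 200 changed genes among those of at least 2 CPM. Counts were drawn from the fitted model with its own dispersions. The check therefore covers the calculation and not the real spread between libraries. With more changed genes, the shares recovered could differ. In the simulated knockout comparison (22693 genes) it called 64 of 66 genes changed 2-fold, 47 of 67 changed 1.5-fold and 34 of 67 changed 1.25-fold, with 8 calls among 22493 unchanged genes. In the simulated overexpression comparison (22702 genes) the calls were 64 of 66, 50 of 67 and 36 of 67, with 13 among 22502. In the simulated comparison of both lines (22695 genes) they were 64 of 66, 50 of 67 and 40 of 67, with 13 among 22495.

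Genes were named by a rule written before the data were examined: genes with a name, an average log2 CPM of at least 1, an adjusted p under 0.05 and groups that did not overlap. As only microRNA genes had names, the 2 largest rises and 2 largest falls among unnamed genes under the same limits were added for each comparison; that addition, and the other microRNA genes given with their values, were chosen after the table was seen. Alternatives were RLE size factors, no low-count filter, a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), a fit of the 2 groups compared, the replicate number as a block, each library left out in turn, and a 2-fold minimum. Robust dispersions and split wild-type libraries were added after the data were seen. Leaving out a library leaves 1 in its group, which is then assumed to vary like the others. The labels give no sequencing batch or date.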

Results

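RNA was sequenced from very young maize ears, up to 0.5 cm long, of 3 genotypes: wild type, a line edited with CRISPR and labelled as a knockout of RHW1, and 1 line labelled as overexpressing RHW1. Each genotype had 2 libraries. The series title places RHW1 upstream of ZCN4 in the control of the width of husk leaves, the leaves that wrap the ear. ZCN4 is a maize relative of TERMINAL FLOWER1, a regulator of inflorescence development. The labels do not say whether the 2 libraries of a genotype came from separate plants, from pools or from 1 RNA sample. The p-values may therefore not cover the spread between plants, and rest only on the spread between these libraries. For each gene that spread was taken mostly from all genes together. Total counts ranged from 21094445 in overexpression replicate 1 to 23999698 in overexpression replicate 2, and 26564 to 26859 genes had at least 1 read in a library. The sources used here do not pair the Zm00001d gene identifiers with gene names, so the levels of RHW1 and ZCN4 were not analysed here, and the genotype labels were not checked against the targeted gene. Among the tested genes, only microRNA genes carried names.

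The overexpression libraries stood furthest from the rest, and the knockout resembled wild type more closely. The first principal component of log2 CPM held 42.1% of the variance and placed both overexpression libraries at 35.9 and 37.5, against -16.8 to -19.0 for the other 4. The second held 18.6% and separated knockout, at -19.4 and -22.4, from wild type, at 20.9 and 21.7. Replicates correlated at 0.990 to 0.991 (Pearson's r of log2 CPM across genes, which are not independent replicates). The 4 pairs of wild type with knockout had values of 0.988, and the 8 pairs with an overexpression library had values of 0.982 to 0.983. Replicates still differed beyond counting noise, with a chi-square per gene of 2.23 to 2.61 where counting alone gives about 1, so no pair was taken for a single library.

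**Figure D1:**
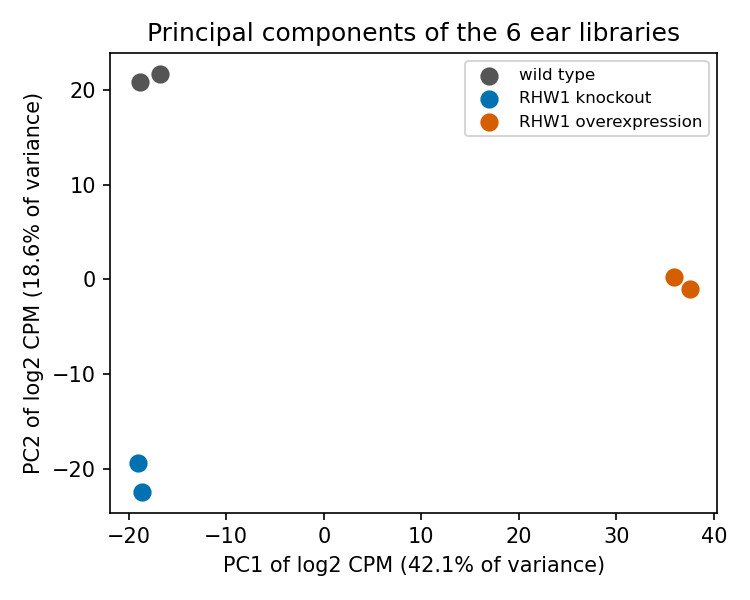
Principal components of log2 CPM over the 22947 tested genes. Each point is 1 library, coloured by genotype; the x axis is the first component (42.1% of the variance) and the y axis the second (18.6%). Replicates lie side by side, overexpression is apart on the first component, and knockout and wild type part on the second.

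The first comparison asked which transcripts differed between the line labelled as a knockout of RHW1 and wild type. In the knockout, 1954 of 22947 tested genes (8.52%) differed from wild type, 926 higher and 1028 lower. Among the named microRNA genes, both zma-MIR528a and zma-MIR408b rose. These are precursor genes of miR528 and miR408, microRNAs known for targeting transcripts of copper proteins such as laccases and plantacyanins. The count of zma-MIR528a rose from 3.67 ± 0.365 CPM in wild type to 6.86 ± 0.758 CPM in the knockout (SD, n = 2), a log2 fold change of 0.90 (SE 0.17, adjusted p = 0.00049, edgeR). That of zma-MIR408b rose from 0.872 ± 0.172 to 2.06 ± 0.261 CPM (SD, n = 2), a log2 fold change of 1.23 (SE 0.35, adjusted p = 0.019, edgeR). The other 8 tested microRNA genes did not pass the test, which at their low counts does not show that they were equal. They included zma-MIR166a, whose family acts on HD-ZIP III leaf polarity genes, at 1.11 ± 0.570 CPM in wild type and 1.252 ± 0.00493 CPM in the knockout. Also among them were zma-MIR160b, of the family that acts on auxin response factors, at 1.00 ± 0.232 and 1.08 ± 0.645 CPM, and zma-MIR168a, of the family that acts on ARGONAUTE1, at 3.57 ± 1.37 and 3.17 ± 0.778 CPM (all SD, n = 2).

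Most knockout changes were small. The median change of the 1954 genes was 1.18-fold and 90% were under 1.49-fold. At 1.5-fold or more there were 53 higher and 136 lower genes, and at 2-fold or more 17 higher and 41 lower. Among unnamed genes with an average log2 CPM of at least 1 whose genotypes did not overlap, the largest rises were those of Zm00001d031236, from 0.936 ± 0.387 to 2.69 ± 0.377 CPM, and Zm00001d022356, from 9.70 ± 4.79 to 23.9 ± 2.86 CPM. The largest falls were those of Zm00001d034776, from 26.6 ± 6.83 to 8.72 ± 1.497 CPM, and Zm00001d029620, from 2.51 ± 0.424 to 0.951 ± 0.0501 CPM (all SD, n = 2). The log2 rise of Zm00001d022356, 1.30, became 1.93 without wild type replicate 1 and 0.876 without wild type replicate 2. In the overexpression line, the libraries had 160 and 612 reads of Zm00001d022356 and 827 and 346 of Zm00001d034776. Both genes thus varied widely within that genotype.

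The count of 1954 depended on every library of the comparison: it was 909 without wild type replicate 1, 1196 without wild type replicate 2, 1052 without knockout replicate 1 and 1267 without knockout replicate 2, and DESeq2 called 975. The call of zma-MIR408b was lost without wild type replicate 1 (adjusted p = 0.056), wild type replicate 2 (adjusted p = 0.153) or knockout replicate 2 (adjusted p = 0.126) and in limma-voom (adjusted p = 0.053), with adjusted p from 0.0068 to 0.153 over the 13 alternatives that gave one. DESeq2 gave zma-MIR408b no adjusted p. It called none of the 4 unnamed genes: Zm00001d022356 and Zm00001d034776 had adjusted p = 0.428 and 0.114, and Zm00001d031236 and Zm00001d029620 were given none. With robust dispersions Zm00001d022356 and Zm00001d034776 also lost their calls (adjusted p = 0.477 and 0.335). Zm00001d022356 and Zm00001d031236 lost their calls without wild type replicate 2 (edgeR adjusted p = 0.053 and 0.093), Zm00001d029620 without wild type replicate 1 (adjusted p = 0.101), and Zm00001d031236 and Zm00001d029620 without knockout replicate 1 (adjusted p = 0.071 and 0.062).

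The second comparison asked which transcripts differed between the line labelled as overexpressing RHW1 and wild type. In the overexpression line, 6698 of 22947 tested genes (29.2%) differed from wild type, 3502 higher and 3196 lower. The same pair of copper-related microRNA genes rose. The level of zma-MIR528a was 10.7 ± 1.04 CPM (SD, n = 2), a log2 fold change of 1.55 against wild type (SE 0.17, adjusted p = 2.21e-09, edgeR). That of zma-MIR408b was 3.35 ± 0.0723 CPM (SD, n = 2), a log2 fold change of 1.94 (SE 0.33, adjusted p = 1.8e-05, edgeR). The other 8 tested microRNA genes again did not pass: zma-MIR166a stood at 1.33 ± 0.153 CPM, zma-MIR160b at 0.828 ± 0.0191 CPM and zma-MIR168a at 3.26 ± 0.742 CPM (SD, n = 2).

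**Figure D2:**
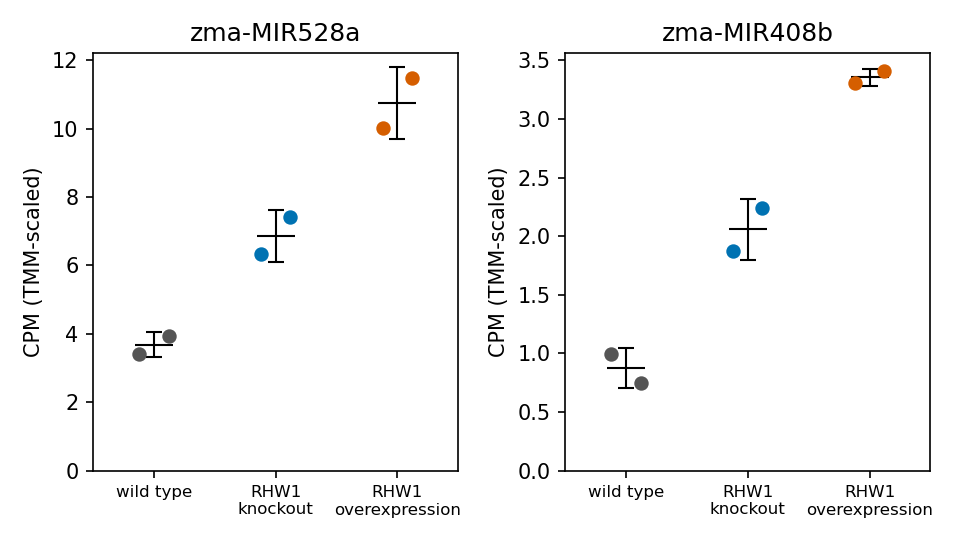
Levels of zma-MIR528a and zma-MIR408b in TMM-scaled CPM (y axes, starting at 0) in the 3 genotypes. Points are libraries, and bars give the mean ± SD of 2. Both genes were lowest in wild type, with 3.67 and 0.872 CPM, and highest in overexpression, with 10.7 and 3.35 CPM.

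Changes in the overexpression line were also mostly small, with a median of 1.23-fold. At 1.5-fold or more there were 463 higher and 596 lower genes, and at 2-fold or more 168 higher and 182 lower. Among unnamed genes with an average log2 CPM of at least 1, the largest rises were those of Zm00001d031875, from 0.700 ± 0.196 to 16.4 ± 0.899 CPM, and Zm00001d051022, from 0.326 ± 0.211 to 6.10 ± 0.781 CPM (SD, n = 2). Zm00001d051022 had only 11 and 4 reads in wild type, and its log2 rise of 4.20 became 5.07 without wild type replicate 1, so its size is uncertain. The 2 largest falls under the same limit ended at or near 0 reads. Zm00001d029091 had 405 reads over both wild-type libraries and 0 in both overexpression libraries, at least 133-fold lower when 3 counts over the group are taken as the floor; the lower limit of the exact two-sided 95% counting interval was 108-fold. Zm00001d001885 fell from 141 reads to 1, a ratio of 139 with an exact 95% counting interval of 24.5 to 5529, and its log2 change of -6.79 became -9.16 without overexpression replicate 1 and -5.85 without overexpression replicate 2. That of Zm00001d029091, -10.66 in edgeR, was -8.61 in limma-voom and -10.07 in DESeq2. Intervals and floors cover counting error only. DESeq2 called 4455 genes.

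The share of genes called rose with expression level in both comparisons with wild type. Tested genes were split by mean expression into 4 groups of equal size. In the highest group, at a median of 90.2 CPM, 19.99% were called in the knockout and 52.1% in the overexpression line. In the lowest group, at a median of 1.65 CPM, the shares were 1.71% and 10.01%. The called genes of the highest group had median changes of 1.14-fold and 1.16-fold, and those of the lowest group of 2.02-fold and 1.999-fold. Small changes of weakly expressed genes may therefore have gone undetected. The simulated check was limited to genes of at least 2 CPM, so their detection was not measured.

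Comparing the overexpression line directly with the knockout line, labelled as gain and loss of RHW1, left the wild-type libraries out of the contrast. Here 6120 genes (26.7%) differed, 3225 higher and 2895 lower in overexpression. The microRNA gene zma-MIR528a was higher in overexpression by a log2 fold change of 0.65 (SE 0.15, adjusted p = 0.0013, edgeR), while zma-MIR408b, at 0.71 (SE 0.29, adjusted p = 0.071, edgeR), did not pass. Among unnamed genes with an average log2 CPM of at least 1, the largest rises were those of Zm00001d032902, from 0.304 ± 0.0771 CPM in the knockout to 8.37 ± 0.119 CPM, and Zm00001d051022, and the largest falls those of Zm00001d029091 and Zm00001d001885, whose knockout levels of 7.22 ± 1.39 and 2.76 ± 0.160 CPM (SD, n = 2) lay near those of wild type. The log2 rise of Zm00001d051022 over the knockout, 3.67, became 4.47 without knockout replicate 1. The log2 fall of Zm00001d001885 from the knockout, -6.63, became about -9 and -5.69 without overexpression replicates 1 and 2, and that of Zm00001d029091, -10.36, was -8.31 in limma-voom and -9.77 in DESeq2. As Zm00001d029091 had 0 reads in overexpression, these sizes depend on how each tool treats 0 counts. No floor was computed for it against the knockout. DESeq2 called 3947 genes.

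Setting the 3 tests side by side placed 5263 of the 8983 genes called in at least 1 comparison by the genotype that stood apart. Overexpression differed from both other genotypes, which did not differ from each other by the test, in 1901 genes that were higher and 1665 that were lower. Knockout alone stood apart in 229 higher and 285 lower genes. Wild type alone stood apart in 329 higher and 328 lower genes. In each of these classes, both tests that passed use the libraries of the genotype that stood apart, so noise in those libraries can add genes. A test that did not pass does not show that the other genotypes were equal. Knockout, wild type and overexpression all differed, with wild type between the others, in 193 genes: 115 lowest in the knockout and 78 lowest in overexpression. In another 333 genes all 3 genotypes differed with wild type lowest or highest; wild type was lowest and overexpression highest in 160 of them, zma-MIR528a included, and wild type was highest and overexpression lowest in 133. Among the 193 genes with wild type in between, only Zm00001d012266 changed at least 2-fold both ways; this gene was singled out after its values were seen. It had 17 and 14 reads in wild type, 1 and 4 in knockout, and 77 and 78 in overexpression, with log2 fold changes of -2.59 (SE 0.68, adjusted p = 0.011, edgeR) and 2.35 (SE 0.41, adjusted p = 2.09e-05, edgeR) against wild type.

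Genes changed in both lines mostly changed the same way. Of 1183 such genes, 496 were higher and 494 lower in both lines, and 193 (16.3%) went opposite ways. Independent lists of the same sizes would share 284 genes in the same direction and 286 in opposite directions. These values assume that every gene is equally likely to be called. The share called rose with expression in both comparisons, so they are too low. Both comparisons use the same wild-type libraries, and in 20 simulations with no change in any group the same-direction overlap averaged 0.25 genes and the opposite overlap 0; such groups give few calls at all, so these values are no yardstick for overlaps between long lists. The correlation of the log2 differences across all tested genes was 0.346, and the simulations gave 0.499 from the shared controls alone. The covariance was 0.0372 against a simulated 0.0205 ± 0.00071 (SD of 20 simulations), a difference of 0.0168. Most of the covariance came from the shared controls. With each line set against a different one of the 2 wild-type libraries, it fell to 0.00798 and 0.0117. Part of the same-direction excess among called genes may have the same source. The covariance covers all tested genes, so it does not measure that part. Without wild type replicate 1 the opposite count was 73 and the same-direction count 463, without wild type replicate 2 they were 97 and 601, and without knockout replicate 1 they were 117 and 559.

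**Figure D3:**
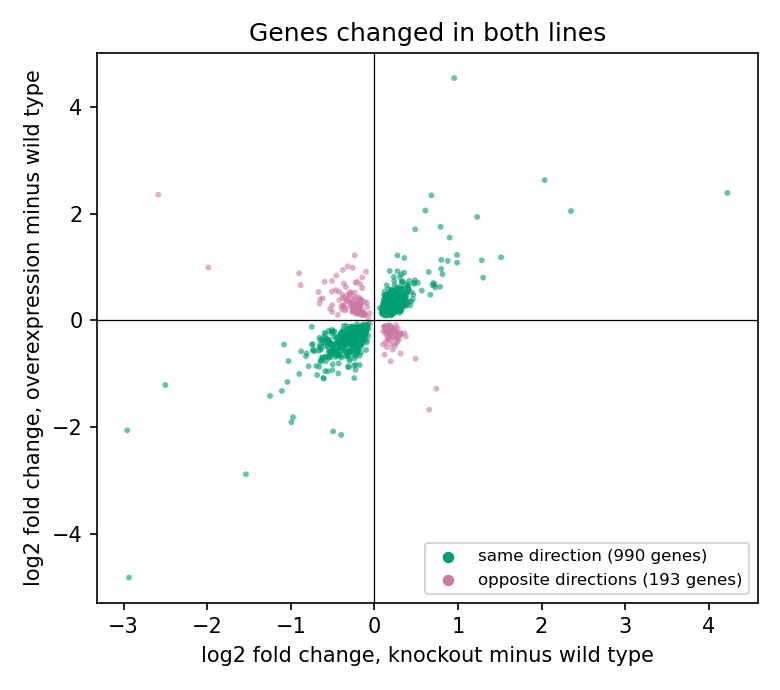
Log2 fold changes against wild type of the 1183 genes changed in both lines, knockout on the x axis and overexpression on the y axis, 1 point per gene. The 990 genes changed in the same direction lie in the lower left and upper right, and the 193 changed in opposite directions in the others; both axes share the same wild-type libraries.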

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

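Robust dispersions and the split of the wild-type libraries were chosen after seeing the data; the others were set before. The counts of changed genes (1954, 6698 and 6120) and of genes changed in opposite directions (193) stayed within 1.5 times of these values with RLE size factors, other low-count filters, limma-voom, fits of only the groups compared and robust dispersions. DESeq2 called 975 genes in the knockout, 4455 in overexpression and 3947 between the lines, every one of them also called by edgeR in the same direction, and 95 in opposite directions. A 2-fold minimum left 58, 350 and 363 genes, 1 of them in opposite directions, because it only removes genes; it moved the higher share of the knockout calls from 47.4% to 29.3%. Leaving out 1 library gave 909 to 2129 genes in the knockout, 4823 to 6754 in overexpression and 4335 to 6027 between the lines, with 73 to 167 in opposite directions; fewer libraries were then tested. The covariance of fold changes ranged from 0.0431 to 0.0820 with 1 library left out and was highest without wild type replicate 1 or 2. It was 0.0682 without a low-count filter and 0.0266 with a filter of at least 1 CPM in 2 libraries. For the filter the cause was not tested. Split wild-type libraries gave covariances of 0.00798 and 0.0117, and 132 and 88 genes in opposite directions. Replicate numbers did not pair the libraries: deviations from group means correlated at -0.00862, -0.0139 and 0.00772 between genotypes. With the replicate number as a block the counts were 1743, 6465 and 5850, with 172 in opposite directions, and the covariance stayed at 0.0372, which a block cannot change in a balanced design. Of 235 values of the 11 named genes over 14 alternatives, 0 changed sign and 13 lost their call, each of these in the knockout comparison. The 235 leave out the DESeq2 values of zma-MIR408b, Zm00001d031236 and Zm00001d029620 in the knockout comparison. DESeq2 gave these no adjusted p and so no call. Counts of the microRNA genes were low, with 17 to 81 reads of zma-MIR408b in a library, and each group had only 2 libraries. The alternatives listed for RHW1, ZCN4 and the gene lists were not run, since these were not analysed here.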

Other observations

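Every test of an explanation below was chosen after the data were seen; for the covariance with split wild-type libraries only the limit was set before its values were computed. Of the microRNA genes known as responsive to copper supply, zma-MIR397a, zma-MIR397b, zma-MIR398a and zma-MIR398b had 0 reads in each library, which allows up to 3 counts in each. The near copy zma-MIR528b had 0 and 11 reads in wild type, 0 and 1 in knockout and 10 and 3 in overexpression, too few for a direction. The 113 tested ENSRNA non-coding genes gave 5 calls in the knockout, all 5 higher, and 9 in overexpression, 7 higher and 2 lower. These were 4.42% and 7.96% of them, beside 8.53% and 29.3% of the Zm00001d genes. In the group of tested genes with the lowest expression, the shares were 1.71% and 10.01%. Expression was not matched between the kinds of gene, so these shares do not show a difference between them. Among the 58 knockout calls of at least 2-fold, replicates of 1 genotype differed by more than 2-fold in 10, and the groups overlapped in 6.

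Genes changed in both lines went in the same direction (990) more often than in opposite directions (193). The shared wild-type libraries were tested as the whole cause by setting the knockout against one wild-type library and overexpression against the other. This removes the noise of a single wild-type library from one of the contrasts. Noise common to both wild-type libraries would remain in both contrasts and was not tested. The covariance fell from 0.0372 to 0.00798 and 0.0117. Most of it thus came from the shared libraries, but it stayed above the limit of 0.005. The covariance covers all tested genes and does not measure the excess among called genes. In both splits, genes called in both contrasts still went mostly the same way. Those calls rest on a single wild-type library per contrast, so the sizes of the overlaps are not interpreted here. A remaining hypothesis, not tested, is that wild type differs from both modified lines in something other than RHW1, such as transformation history or the stage of the ears, since the labels do not say whether the wild type were siblings of the lines.

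The precursor genes zma-MIR528a and zma-MIR408b were higher in both lines than in wild type. A single low wild-type library does not account for this: without either one, the smallest of the 8 log2 fold changes was 0.80. Recovery that was better for all microRNA precursors alike is also argued against. The summed CPM of the other 8 tested microRNA genes differed from wild type by log2 -0.077 in the knockout and -0.053 in overexpression. These 8 were already known not to pass the test in either comparison, so better recovery of only some precursors was not tested. A background or copper status shared by both modified lines may contribute and cannot be told apart from an effect of RHW1. The difference of zma-MIR528a between the lines was 0.72 of that between knockout and wild type. For this gene, a shared background alone would leave part of the overexpression rise open. The difference of zma-MIR408b between the lines did not pass (log2 0.71, adjusted p = 0.071, edgeR), so the same cannot be said of it.

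In the overexpression line 9 genes were nearly switched: 4 had at most 3 reads on average at mean depth against at least 30 in both other genotypes, among them Zm00001d029091 and Zm00001d001885, and 5 showed the reverse, among them Zm00001d041007 (129 and 100 reads against 0 to 3) and Zm00001d024441 (91 and 88 reads against 1 to 4). The same limits gave 0 such genes in wild type and 0 in the knockout. One aberrant library is argued against for the near-on genes, as 5 of the 5 had at least 20 reads at mean depth in each overexpression library; for the near-off genes the limit on the mean already requires both libraries to be low, so this was not a test. One block of neighbouring gene identifiers, as a segment linked to the transgene might give if identifiers follow genome order, is also argued against as the whole cause, since only 2 of the 9 had another within 100 identifier numbers. Different alleles or gene content in the stock of the overexpression line remain a candidate explanation for all 9, and cannot be told apart from regulation by RHW1, because counts hold no sequence variants.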
